A study of Mus musculus with 12 samples.

How the data were processed

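The series is a time course of microRNA (miRNA) profiles of Kupffer cells, the resident macrophages of the liver, from BALB/c mice before and after partial hepatectomy, the surgical removal of part of the liver. Per the labels' protocols, each sample was a pool of sorted cells from 5 animals, although the series text marks the number of animals per pool as uncertain. Total RNA was isolated with a column kit and concentrated, and 100 ng was prepared with the nCounter miRNA assay and hybridised with the reporter and capture probes of the mouse version 1.5 panel, per the labels' protocols. In this assay each miRNA is joined to a tag and read by counting single colour-coded reporter molecules, without amplification or sequencing. The counter settings, the normalization and any filter applied to the samples are not given in the sources used here.

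The only deposited file used here was the reporter library file of that panel, the definition with which the instrument's software turns a barcode into a target name. Per the file headers it has 8 columns, which give each probe's class, target sequence, barcode, name, probe identifier, species, accession and type, and 0 of these columns is named for a sample. It gives no value for any of the 12 samples. The depth per sample is therefore unknown, and no expression level, fold change, error, interval or p-value was computed. The count-based test planned for the comparisons of days 1, 3 and 7 with the time before surgery, and the planned tests of gene lists, were not run for this reason. The per-sample counts were not analysed here.

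From the library file, the records were counted by class and the names of jointly detected miRNAs were separated at the plus sign. Length and GC content were computed from each target sequence, which the file writes as DNA from the 5′ end. A seed was defined as bases 2 to 8 from the 5′ end, the part of an miRNA that chiefly sets which mRNAs it pairs with, and seeds were compared over all mouse records. Pairs of mouse targets were compared base by base from the 5′ end over the length of the shorter target, without gaps, and called near-identical with at most 1 mismatch. The alternatives were a seed of bases 2 to 7, at most 2 mismatches, and distinct sequences or names in place of records. A further alternative, chosen after seeing the data, called a pair near-identical at 1 edit at most (a substitution, an insertion or a deletion), with up to 2 bases at the 5′ end of either target left out and any overhang at the 3′ end ignored. The pair search was tested on 550 simulated sequences with 50 planted near-identical pairs, of which 50 were recovered with 0 false pairs. The seed search grouped all 50 planted pairs, but every planted difference lay after the seed, so this outcome was fixed in advance. The planted pairs were also of equal length, unlike some pairs of the panel. The gapped search was tested on 140 simulated sequences with 40 planted pairs, of which 40 were recovered with 0 false pairs. Its planted pairs lacked an inner base or the first base, and no shift of 2 bases was planted. All computations used Python 3.11.15.

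miRNA names were looked up by symbol or synonym in a RefSeq gene table of the mouse assembly GRCm38.p6, after removal of the arm suffix. Of the 577 names, 538 matched, or 93.2%, and 39 did not. The library file names no genome build, so no coordinates are given. The 9 miRNA lists (myeloid and macrophage, hepatocyte, endothelial, stellate and stromal, erythroid, lymphoid, miR-17 cluster and paralogs, p53 and arrest, and let-7) were fixed before the data were examined. With no sample values, the rule for naming miRNAs was to take the list members, the largest seed families and the near-identical pairs in alphabetical order. The rule did not cover the joint records, which are named below as well. Its upper limit on the number of names was not kept, if that limit covers every miRNA named.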

Results

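miRNA profiling of Kupffer cells was laid out as a time course around partial hepatectomy, with 12 pooled samples in 4 groups. The group taken before surgery had 3 pools, the group at day 1 had 3, the group at day 3 had 2 and the group at day 7 had 4. Each pool held sorted cells of 5 BALB/c mice according to the sample labels, a number that the series text marks as uncertain. The design implies a comparison of each time after surgery with the time before it. None of these comparisons was made, since the values of the samples were not analysed here. The measurements below describe the probe panel with which the samples were profiled. They concern which miRNAs the panel named, which of them shared a record and how similar the target sequences were, and they say nothing about the level of any miRNA in Kupffer cells. The panel is a fixed design, so its values have no replicates and no sampling error.

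The panel held 652 probe records, of which 566 were directed at mouse miRNAs. A further 33 records were directed at viral miRNAs, 23 of murine cytomegalovirus and 10 of murine gammaherpesvirus. There were 4 records for the mRNAs Actb, Gapdh, Rpl19 and B2m, which serve as housekeeping controls, and the accession of each of the 4 belonged to the gene of that name in RefSeq. The remaining controls were 6 positive and 8 negative hybridisation controls, 6 ligation controls, 3 binding and 3 purification controls, and 3 spike-in targets taken from plant and nematode miRNAs. The names of the positive controls carried numbers in a graded series from 128 for POS_A to 0.125 for POS_F. Finally, 20 records were reserved barcodes without a target. In total 626 records had a target sequence, and 0 of these sequences occurred more than once.

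The 566 mouse records named 577 miRNAs, which is the number of mouse miRNAs given in the description of the series. The difference came from 9 records that each stood for more than 1 miRNA. Of these, 7 named 2 miRNAs and 2 named 3, so that 20 miRNAs had only a record shared with another. Each joint record gave a single target sequence, which was used here for every miRNA it named. How strongly each of its miRNAs is detected was not measured. miR-17, a member of the miR-17 cluster known for its role in cell proliferation, shared its record with miR-106a. In the same way miR-20a was joined with miR-20b, and miR-181b with miR-181d. The records with 3 names were miR-297a with miR-466f and miR-669b, and miR-467h with miR-669d and miR-669l. The other 557 records named a single miRNA.

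The 9 miRNA lists, drawn up for cell types, the miR-17 cluster and its paralogs, p53 and arrest, and let-7, were fully represented on the panel. All 53 members had a record, 50 of them a record of their own. The myeloid and macrophage list had 10 of 10 members, among them miR-223, which is abundant in myeloid cells, miR-155 and miR-146a, which are induced by inflammatory signals in macrophages, and miR-511, which lies in an intron of a macrophage mannose receptor gene. The lists of other liver cell types were likewise covered. The hepatocyte list had 6 of 6 members, including miR-122, the predominant miRNA of hepatocytes, and the endothelial list had 4 of 4, including both arms of miR-126. The stellate and stromal list had 5 of 5 members, including miR-143 and miR-145. The erythroid list had 3 of 3, including miR-451 and miR-144, and the lymphoid list had 4 of 4, including miR-150. The list of the miR-17 cluster and its paralogs had 9 of 9 members, of which 2, miR-17 and miR-20a, had only a joint record. The list of p53-responsive miRNAs had 3 of 3 members and the let-7 list had 9 of 9. In the lymphoid list, miR-181b was the 1 member with a joint record.

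The target sequences were of mature miRNA size. Their median length was 22 bases with a range of 16 to 27, and 497 of the 566, or 87.8%, were 21 to 23 bases long. GC content had a median of 47.8%, with quartiles of 40.9% and 57.1% and extremes of 19.0% and 94.7%. By list, the median GC content was 36.4% for the erythroid miRNAs, 40.9% for the myeloid and macrophage list and for let-7, 43.5% for the miR-17 cluster list and 45.5% for the hepatocyte list. It was 46.6% for the endothelial list, 47.8% for the lymphoid and the p53 lists and 52.2% for the stellate and stromal list. Within the erythroid list, miR-451 had 36.4% GC and miR-486 had 63.6%. miR-122 had the target sequence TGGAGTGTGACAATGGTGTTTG, with 45.5% GC, and miR-223 had TGTCAGTTTGTCAAATACCCCA, with 40.9%.

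A minority of the targets shared a seed with another. Targets with the same seed are called a family here, and no other relation between them was tested. The 566 targets had 457 different seeds, 62 of which occurred in more than 1 record, and 171 targets, or 30.2%, shared their seed with another. The largest family was let-7, with 10 records that comprised let-7a to let-7g, let-7i, miR-98 and miR-1961. It was followed by the 7 records of the miR-15 and miR-16 family, which also took in miR-195, miR-322, miR-497 and miR-1907. There were 4 families of 6 records each. These were miR-30a to miR-30e with miR-384-5p, the miR-34 and miR-449 family, the miR-25 and miR-92a family, and the family of miR-291a-3p, miR-294, miR-295, miR-302a, miR-302b and miR-302d. Of the 53 list members, 32 shared a seed with another target. All 9 members of the let-7 list and all 9 of the miR-17 cluster list did so. The numbers were 3 of 4 in the lymphoid list, 2 of 3 in the p53 list, 2 of 4 in the endothelial list, 4 of 10 in the myeloid and macrophage list, 2 of 6 in the hepatocyte list, 1 of 5 in the stellate and stromal list and 0 of 3 in the erythroid list. No test was made of these shares, because the lists were built on different principles, some by family and some by cell type.

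Near-identical targets were searched base by base from the 5′ end without gaps. Among the 566 mouse targets, 28 pairs differed by a single base in this comparison, and these pairs involved 51 targets, or 9.01%. With up to 2 mismatches allowed, there were 59 pairs, which involved 87 targets. In 25 of the 28 pairs at a single mismatch both targets were of equal length, and in 3 they were not. Counting positions from 1 at the 5′ end and giving the base of the first-named target first, let-7a and let-7c differed by A19G, let-7a and let-7e by T9G, let-7a and let-7f by G12A, and let-7b and let-7c by G17A. let-7a, with the sequence TGAGGTAGTAGGTTGTATAGTT, had 3 partners at a single mismatch. miR-101a, of the hepatocyte list, differed from miR-101b by A16G, and miR-19a differed from miR-19b, both of the miR-17 cluster, by T11C. Of the 53 list members, 8 had such a partner. These were let-7a, let-7b, let-7c, let-7e, let-7f, miR-19a, miR-19b and miR-101a. The other 6 lists had 0 members with such a partner in the ungapped comparison. miRNAs that share a record, such as miR-181b with miR-181d or miR-17 with miR-106a, were not compared with each other. Their similarity is outside all of these counts of pairs and partners. With gaps and a shift of up to 2 bases at the 5′ end allowed, a setting chosen after seeing the data, 36 pairs were within 1 edit. They included miR-181a and miR-181c of the lymphoid list. In that setting 10 list members had a partner, and the myeloid and macrophage, endothelial, stellate and stromal, erythroid and p53 lists each had 0. These zeros do not carry over to the ungapped comparison with up to 2 mismatches. There, further list members had a partner, among them miR-146a (myeloid and macrophage), miR-148a (hepatocyte) and miR-34c (p53). Partners were not counted by list with up to 2 mismatches. Other pairs at a single mismatch included miR-100 and miR-99a, which differed by A16T, miR-103 and miR-107, by G22C, and miR-10a and miR-10b, by T12A.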

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

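No paired analysis was possible because no sample values were analysed. The labels number the pools within each time group and do not tie a number to a shared animal, batch or day. Without sample values, the alternatives planned for the comparisons between time groups (other normalizations, filters on low counts, pseudocounts, other samples in the fit, and leaving out each replicate) were not run. For the panel, counting distinct sequences gave 566 mouse targets, as did counting records, and counting names gave 577. With a seed of bases 2 to 7, 221 targets shared a seed, against 171 with bases 2 to 8. Allowing 2 mismatches raised the number of near-identical pairs from 28 to 59, which involved 87 targets. A comparison chosen after seeing the data, with gaps and a shift of up to 2 bases at the 5′ end allowed, gave 36 pairs within 1 edit, 8 more than the ungapped one, which involved 63 targets. Restricting the search to distinct sequences left 171 targets sharing a seed and 28 pairs and tests nothing, because no sequence was repeated. How far near-identical targets cross-hybridise in the assay was not measured.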

Other observations

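In the ungapped comparison, the single-base differences between near-identical targets all lay outside the seed. Of the 28 pairs, 0 differed at bases 1 to 8 and 28 differed further towards the 3′ end, at positions 9 to 22 with a median of 13.5. Each of these pairs therefore shared its seed. Of the 8 pairs found only with a gap or a shift, 2 shared a seed and 6 did not. The seed was read at fixed bases, and a shift at the 5′ end moves that window. The count of 6 therefore does not show where such pairs differ. The pattern in the ungapped pairs was noticed in the sequences and was not tested against a model of miRNA families.

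Compared base by base from the 5′ end without gaps, the closest viral and mouse targets differed by 6 bases over the shorter of the pair. A seed was shared by 1 pair, mghv-miR-M1-4 and miR-151-5p. How many shared seeds would arise between unrelated sequences was not computed. These targets were named after their sequences had been compared.

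A number followed the name in 606 records and was 0 in 602 of them. The 4 others were miR-34c with 0.124, miR-155 with 0.022, let-7a with 0.013 and miR-543 with 0.009. The file does not define this number, and a reading of it as a correction for the probe's own background was not testable without counts. miR-155, let-7a and miR-34c were also members of the lists fixed in advance. The lists had 53 members on the panel, against 566 mouse records, and this overlap was not tested.

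Among the 39 miRNA names that did not match a gene in RefSeq were miR-720, miR-1274a, and miR-1937a, miR-1937b and miR-1937c, together with 11 names from miR-2132 to miR-2183. In that range miR-2136, miR-2137 and miR-2139 did match. Both arms of miR-466a and of miR-590 were also among the unmatched names. The match was by name alone, and the sequences were not searched in a genome. These names were picked after the list of unmatched names had been seen.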
